A study of Rattus norvegicus with 16 samples.

How the data were processed

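Total RNA of synovial tissue from rat knees was sequenced after preparation with a directional RNA library kit (NEBNext Ultra II Directional) on an Illumina NextSeq instrument, per the labels' protocols. The 16 libraries fell into 4 groups of 4 by their titles, which give the knee (MIA or contralateral), the treatment (vehicle or inhibitor) and a sample number from 1 to 4. The compound, its dose and its schedule are not given in the sources used here.

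Each library had 1 deposited file in the format of Salmon, per the file headers. The submitters' processing notes name fastp 0.20.1, Salmon 1.4.0, DESeq2 1.30.0 and the genome build mRatBN7.2, and the release of the transcript set and Salmon's options are not given in the sources used here. The deposited estimated counts per transcript are the authors' expected counts, which need not be whole because Salmon divides reads that match several transcripts, and they are not scaled between libraries. The deposited TPM values are scaled by effective length to a fixed total per library, per the file headers. The deposited effective lengths and transcript lengths are in bases. Between 26.7% and 34.8% of the values above 0 in a library were whole numbers, within a tolerance of 1e-06. The files held the same 46726 Ensembl rat transcripts in the same order, and 8648 of them had no count in any library.

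Transcript identifiers could not be joined to genes: the files do not pair them with names, and the table of rat genes given for this work had 0 entries in its column of Ensembl identifiers. The tests therefore ran on transcripts, as the plan fixed before the data were examined provided for. The gene lists planned for set tests and library scores, the gene of the inhibited protein, and covariates from lists of muscle and fat markers are not analysed here. The 4 transcripts given by identifier are the 2 largest rises and 2 largest falls on the log2 scale in the MIA comparison of vehicle rats among transcripts with an adjusted p under 0.05, a mean of at least 1 CPM in either group and no overlap between the groups' libraries. This rule was fixed before the data were examined, except that it asked for 10 of each direction with a gene symbol, and in every comparison.

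Expected counts were rounded to whole numbers. Transcripts were kept by edgeR's filterByExpr with the 4 groups, which left 26956 holding 99.7% to 99.9% of a library's counts, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3; glmQLFit with robust=TRUE), two-sided, with 1 mean per group over all 16 libraries, so that all groups shared an estimate of the spread, and with no covariate. P-values were adjusted by Benjamini-Hochberg over the transcripts of a comparison at 0.05. The comparisons were MIA with contralateral knees in each treatment and averaged over both, inhibitor with vehicle in each kind of knee, and the interaction. Standard errors are the absolute log2 change divided by the root of the F statistic. Principal components were computed on log2 CPM. Fold changes against a group with no counts are given as bounds with a floor of 3 counts per library, the upper 95% limit for a count of 0, which covers counting error only, as do the exact (Clopper-Pearson) binomial intervals at 95%. Library measures were compared by exact two-sided permutation tests of 4 against 4 libraries.

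The set of co-varying transcripts was defined after the data were seen, on log2(CPM + 1): the seed was the transcript with the largest SD over all 16 libraries among those with a mean of at least 1000 CPM, and members had a correlation of at least 0.9 with it in their deviations from the group means, so that group differences played no part in membership beyond the choice of the seed. An earlier definition, with the seed chosen by its spread within groups, was tried first and replaced after its members were seen to follow the 4 libraries that lie apart on the second principal component. The set that was kept also had its highest share within a group in these libraries, except in contralateral vehicle knees, where replicate 1 had the lowest share. Correlations between comparisons that share libraries were set beside 10 simulated data sets with no change, drawn with the observed means, library sizes and dispersions, and beside fits with the shared libraries split into pairs.

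The test was checked on simulated data for the MIA comparison in inhibitor rats over 26956 transcripts, with 200 transcripts of at least 1 CPM changed. edgeR called 46, of which 41 of 100 changed 4-fold and 5 of 100 changed 2-fold were recovered, with 0 false calls, and the median estimate for 4-fold changes was 2.04 on the log2 scale. DESeq2 called 216, of which 125 were false, and limma-voom 46, of which 1 was false.

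Sample numbers are shared between groups. Whether they pair the knees was checked from the correlation of the libraries' deviations from their group means, before blocked fits were compared. In inhibitor rats the correlations of same-numbered knees were 0.29, 0.15, 0.16 and 0.51, all over 0.1, so the numbers were taken to pair these knees from the data, since the labels do not say that a number marks a rat. This pairing is assumed, not shown. Same-numbered MIA libraries of different treatments ran from -0.25 to 0.26, so values of this size also arise between treatments. The 0.51 joins replicate 4 of both inhibitor groups, which lie apart together on the second principal component. The depth ranged from 15614902 to 37063328 estimated counts per library. At that depth a count of 3 corresponds on average to between 0.0849 and 0.144 CPM in the 4 groups.

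Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test), limma-voom with quality weights, limma-trend on log2(TPM + 1) for transcripts with at least 1 TPM in 4 libraries, DESeq2 size factors and upper-quartile factors in the edgeR fit, no filter beyond a count above 0, a filter of at least 1 CPM in 8 libraries, robust=FALSE, effective lengths as an offset, only the groups compared, a replicate block as a fixed and as a random effect, and leaving out each library. Alternatives added after the data were seen were leaving out the 4 libraries that lie apart on the second principal component, a term for them, leaving out the 100 most abundant transcripts, and the mean log2 CPM of the co-varying set as a covariate. Other splits of the libraries were refitted for each comparison, all 35 for 4 against 4 and 60 drawn with a fixed seed for the interaction and for both treatments.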

Results

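Synovial tissue RNA of rats was profiled in 16 libraries, 4 from each of 4 groups. Each rat received 2 mg of monoiodoacetate (MIA) in 50 µl of saline in 1 knee, a chemical used to model osteoarthritis, while the contralateral knee received 50 µl of saline, and tissue was collected after 4 weeks. The labels give each knee a treatment of vehicle or inhibitor, and the title of the series names fatty acid binding protein 5, an intracellular carrier of lipids, as the protein inhibited. The groups were contralateral knees with vehicle, MIA knees with vehicle, contralateral knees with inhibitor and MIA knees with inhibitor. The values were estimated counts for 46726 transcripts, of which 26956 passed the filter on low counts and were tested. Library totals were 27641038 to 31142101 counts in contralateral vehicle, 29416041 to 37063328 in MIA vehicle, 15614902 to 27916996 in contralateral inhibitor and 21619501 to 36668131 in MIA inhibitor knees. A transcript is written as called where its adjusted p was under 0.05. The files do not pair the transcript identifiers with gene names, so transcripts are described as groups, and 4 are given by identifier. The labels do not state that the 4 libraries of a group came from separate rats, so the p-values measure the spread between these libraries.

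The libraries differed in ways that moved with 1 group. The 4 contralateral vehicle libraries lay apart from the other 12 on the first principal component of log2 CPM, which held 31.4% of the variance, with a mean score of 187.8 ± 46.4 (SD, n = 4) against -76.2 ± 83.6 (SD, n = 4) in MIA vehicle knees. Their 100 most abundant transcripts held 47.8% ± 5.31 (SD, n = 4) of the counts, against 31.5% ± 1.88 in MIA vehicle knees, 28.5% ± 3.00 in contralateral inhibitor knees and 28.0% ± 3.90 in MIA inhibitor knees (SD, n = 4 each). A second division was seen on the second component, which held 16.9% of the variance and set 1 library of each group below all others. These were replicate 1 of both vehicle groups, with scores of -111 and -116.1, and replicate 4 of both inhibitor groups, with scores of -192.7 and -163.6.

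**Figure D1:**
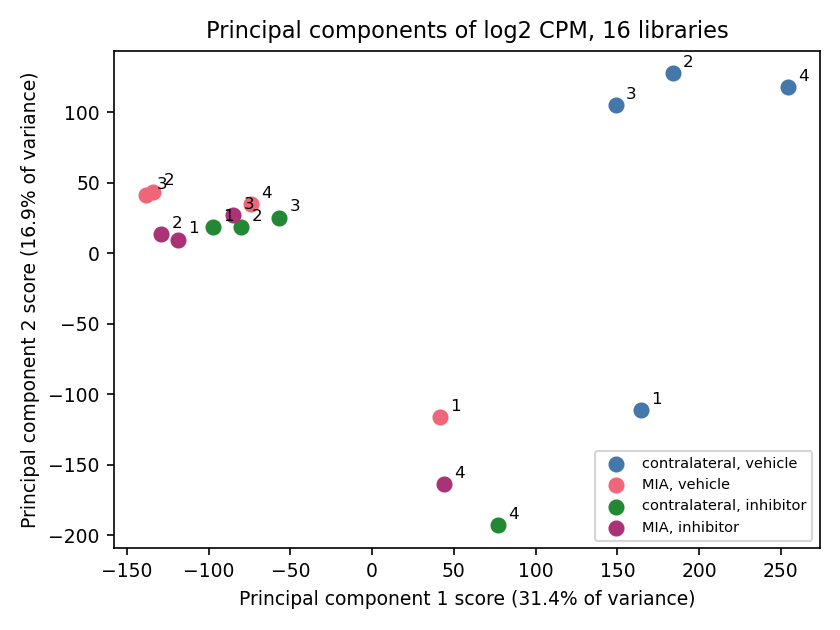
Scores of the 16 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, without unit, with the share of variance on each axis, coloured by group and numbered by replicate. The 4 contralateral vehicle libraries lie furthest to the right, and replicate 1 of both vehicle groups and replicate 4 of both inhibitor groups lie at the bottom.

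A set of 125 transcripts rose and fell together between libraries. These were the transcripts whose deviations from their group means followed, with a correlation of at least 0.9, those of the most variable transcript with a mean of at least 1000 CPM, a choice made after the data were seen. They held 27.9% ± 5.67 (SD, n = 4) of the counts in contralateral vehicle knees, against 1.52% ± 2.30 in MIA vehicle knees, 1.4% ± 1.51 in contralateral inhibitor knees and 1.09% ± 1.55 in MIA inhibitor knees (SD, n = 4 each). The contralateral vehicle libraries ranged from 19.8% (95% exact binomial interval 19.76 to 19.79) to 32.9% (32.92 to 32.95), and the other 12 from 0.0357% (0.0350 to 0.0364) to 4.90% (4.889 to 4.903), intervals that cover counting error only. In the other groups the library that lies apart on the second component had the highest share. These shares were 4.90% in MIA vehicle replicate 1, 3.54% in contralateral inhibitor replicate 4 and 3.32% in MIA inhibitor replicate 4. In contralateral vehicle knees, replicate 1 had the lowest share, 19.8%. The seed of the set was chosen for its spread over all 16 libraries, so no p is given for the differences between groups in this share.

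**Figure D2:**
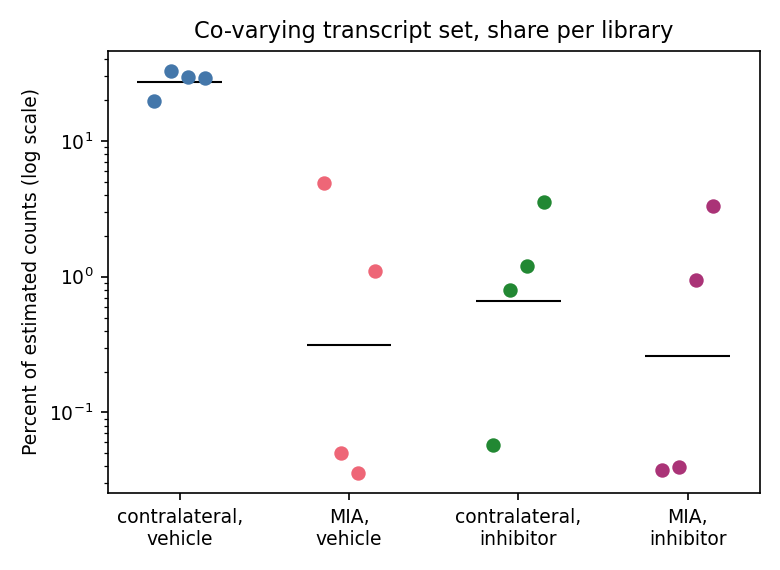
Percent of each library's estimated counts held by the 125 co-varying transcripts (y axis, log scale), by group (x axis), with 1 point per library and a line at the geometric mean of the 4 libraries. The contralateral vehicle libraries lie between 19.8% and 32.9%, and all other libraries at or below 4.90%.

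The first comparison asked what differed between the MIA knee and the saline knee in vehicle-treated rats. In it 7860 of 26956 transcripts were called, of which 4289 were higher and 3571 lower in the MIA knees, and the median absolute log2 change of these was 1.42. The larger direction depended on the scaling and on single libraries, since with DESeq2 size factors in the edgeR fit 3520 were higher and 4214 lower, and without contralateral vehicle replicate 4 these numbers were 2469 and 3248. Changes of more than 4-fold were found for 1182 of the higher and 1292 of the lower transcripts. The 2 transcripts with the largest rises were ENSRNOT00000059673.6 and ENSRNOT00000011727.7, and those with the largest falls were ENSRNOT00000089142.2 and ENSRNOT00000117239.1. ENSRNOT00000059673.6 (4889 bases) had a level of 35.3 ± 8.75 CPM (SD, n = 4) in MIA knees and no count in any contralateral vehicle library, so it was at least 245-fold higher against a floor of 3 counts per library (edgeR adjusted p = 3.07e-07). It was also present in both inhibitor groups, at 25.7 ± 7.22 CPM in contralateral and 29.9 ± 6.43 CPM in MIA knees (SD, n = 4 each). ENSRNOT00000011727.7 (1790 bases) had no count in any of the 8 contralateral libraries and was found in all 8 MIA libraries, at 33.3 ± 11.3 CPM with vehicle and 19.3 ± 37.0 CPM with inhibitor (SD, n = 4 each), where 1 library held 74.8 CPM and the other 3 held 0.413 to 1.42 CPM. In vehicle rats this was a rise of at least 232-fold (edgeR adjusted p = 0.0147), and its adjusted p was 0.0834 once the mean level of the 125 co-varying transcripts was added to the fit, with an estimated log2 change of 14.4 ± 4.16 (SE) against 12.9 ± 3.04 (SE) without it. As it had no count in contralateral knees, these estimates do not measure the size of its change. ENSRNOT00000089142.2 (2185 bases) and ENSRNOT00000117239.1 (4530 bases) were found in the contralateral vehicle libraries alone, at 94.7 ± 61.1 and 94.2 ± 41.6 CPM (SD, n = 4 each), and had no count in the other 12 libraries. They were at least 1116-fold and at least 1109-fold lower in MIA vehicle knees (edgeR adjusted p = 0.00109 and 0.000361). These bounds cover counting error only. The counts of both falls and of ENSRNOT00000059673.6 were not whole, so Salmon divided their reads with other transcripts. An estimate of 0 may also come from that division, which was not tested, so absence of these transcripts is not established.

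**Figure D3:**
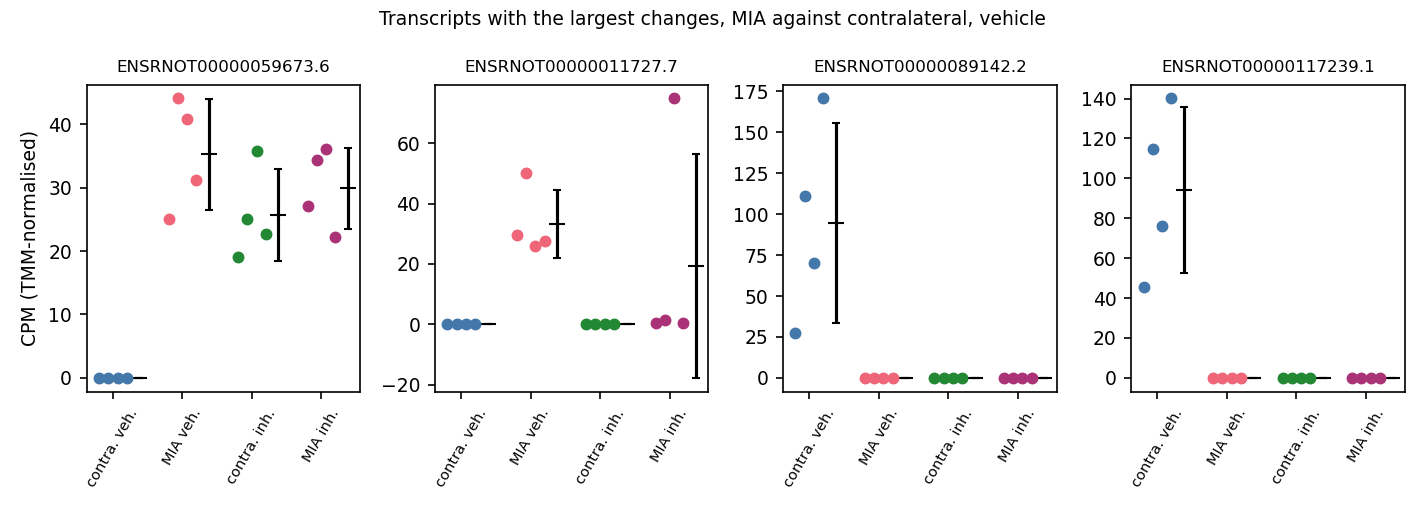
TMM-normalised CPM (y axis) of the 2 transcripts that rose most and the 2 that fell most between contralateral and MIA vehicle knees, by group (x axis), with 1 coloured point per library and, to the right of each group, its mean and SD in black. The 2 that fell are above 0 in the contralateral vehicle libraries alone, and ENSRNOT00000011727.7 is above 0 in MIA libraries alone.

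Transcripts of low abundance were called less often in vehicle rats, and more of those called were higher than lower. Of the 1536 tested transcripts with a mean of at least 100 CPM, 370 rose and 339 fell, and of the 10508 between 10 and 100 CPM, 2326 rose and 2249 fell. Of the 10083 between 1 and 10 CPM, 1339 rose and 885 fell, and of the 4829 below 1 CPM, 254 rose and 98 fell. The 125 co-varying transcripts had a median log2 change of -4.82 with a median SE of 1.97, and 29 of them were called, all lower in MIA knees. All 4 MIA vehicle libraries lay above all 4 contralateral vehicle libraries for 4623 of the tested transcripts and below them for 4028, where chance gives 385 in each direction. The test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and the median log2 change over all tested transcripts was 0.26 with TMM scaling and 0.10 with DESeq2 size factors, so changes are relative to that shift of -0.16. The number called was 2015 with the mean level of the co-varying set as a covariate. That level was 8.84 to 10.2 in the contralateral vehicle libraries and 0.645 to 6.64 in the others, as log2(CPM + 1). The covariate thus largely repeats the group, so the lower count does not show that the set accounts for the calls. With limma-trend on log2(TPM + 1), which differs in test, scale and filter at once, 14001 were called, 12179 of them higher and 1822 lower. On counts limma-voom called 12910.

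In inhibitor-treated rats the same comparison of MIA with contralateral knees called 1 transcript. It was at 0.522 CPM on average in MIA knees, from 0.327 to 0.678 CPM, and had no count in the 4 contralateral inhibitor libraries, with an edgeR adjusted p of 0.0301 (n = 4 against 4), and it was lower in the MIA knees of vehicle rats, with a log2 change of -4.06 ± 0.53 (SE). An unadjusted p under 0.05 was found for 1449 transcripts, where 1348 are expected by chance, and the median SE of a log2 change was 0.46, close to that in vehicle rats. All 4 MIA inhibitor libraries lay above all 4 contralateral inhibitor libraries for 694 tested transcripts and below them for 388, where chance gives 385 in each direction. The 125 co-varying transcripts had a median log2 change of -0.39 with a median SE of 1.71, and none was called with edgeR, with 0 of them under an unadjusted p of 0.05. Simulated counts for this comparison over 26956 transcripts gave 41 of 100 transcripts changed 4-fold and 5 of 100 changed 2-fold as called, with 0 false calls, so changes of 2-fold were mostly not detectable with 4 libraries per group. Other tools called more, 328 with DESeq2 (125 of its 216 calls in the simulated counts were false), 358 with limma-voom (1 of its 46 calls in the simulated counts was false) and 19 with limma-trend. With the sample number as a block, which was taken to pair the knees in these rats, no transcript was called with a fixed effect and 19 with a random effect, 16 higher and 3 lower in MIA knees. An unadjusted p under 0.05 was found for 1896 transcripts with the fixed effect in edgeR and for 2711 with the random effect in limma-voom. The former exceeds the 1449 of the unpaired edgeR fit. The latter has no unpaired fit of the same kind beside it. Unpaired limma-voom with quality weights, which the random-effect fit did not use, gave 3372. The number was 0 without contralateral vehicle replicate 2, 3 or 4, MIA vehicle replicate 2 or 4, or MIA inhibitor replicate 2, 3 or 4, and it was 3 without contralateral vehicle replicate 1, 4 without contralateral inhibitor replicate 2, 5 without MIA inhibitor replicate 1 and 6 without contralateral inhibitor replicate 4. Without the 4 libraries that lie apart on the second component, an alternative chosen after the data were seen, 91 transcripts were called, 80 of them higher in MIA knees and 11 lower.

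**Figure D4:**
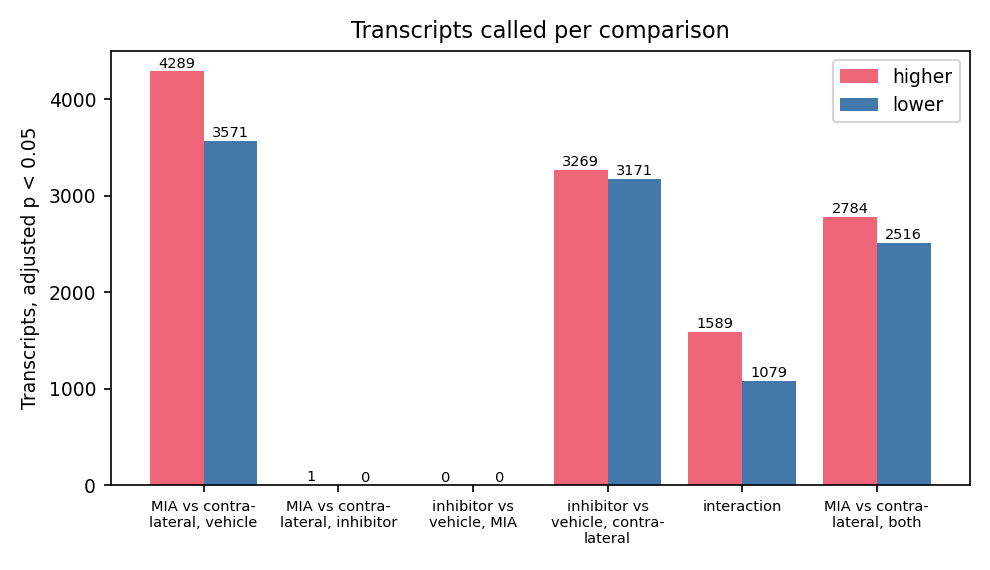
Number of transcripts with an adjusted p under 0.05 (y axis) in each of the 6 comparisons (x axis), as bars for higher and lower levels in the first-named condition, with the numbers above the bars. The comparisons that contain the contralateral vehicle libraries have between 2668 and 7860 transcripts in total, and the 2 that do not contain them have 1 and 0.

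The size of the MIA change was then compared between the treatments. The change differed between inhibitor and vehicle rats for 2668 transcripts by the interaction test, 1589 with a higher and 1079 with a lower log2 change in inhibitor rats. The test could not assess ENSRNOT00000089142.2 and ENSRNOT00000117239.1, which had no count in either inhibitor group. Their interactions were 14.4 on the log2 scale with SEs of 39914 and 27009. In the mean of both treatments' MIA changes their SEs were 19859 and 13438, so they were not called there either. The interaction test also could not assess ENSRNOT00000011727.7, which had no count in either contralateral group. Its interaction was -0.79 on the log2 scale with an SE of 4105. The 125 co-varying transcripts had a median interaction of 4.38 on the log2 scale with a median SE of 2.50, and none was called with edgeR, while 28 had an unadjusted p under 0.05. The mean of both treatments' MIA changes, the contrast that the design text of the series describes, called 5300 transcripts, 2784 higher and 2516 lower in MIA knees, and with DESeq2 size factors 2366 were higher and 2997 lower. All 8 MIA libraries lay above all 8 contralateral libraries for 198 tested transcripts, 190 of them called, and below them for 29 transcripts, all called. Within each treatment on its own, the MIA libraries lay above the contralateral ones in both treatments for 344 transcripts, where independent treatments would give 119, and below them for 58, where independent treatments would give 58.0. Across all tested transcripts, which are not independent replicates, the MIA changes of the treatments had a Pearson correlation of 0.15 and shared their sign for 59.2%, and the slope of the inhibitor rats' change on the vehicle rats' change was 0.0953. Among the 7860 called in vehicle rats the correlation was 0.34 and the slope 0.11. Among the 5300 called in both treatments together these were 0.60 and 0.29, a selection on the mean of both changes that itself favours agreement. The interaction count rested on single libraries, since it was 5484 without contralateral vehicle replicate 1 and between 1451 and 1735 without contralateral vehicle replicate 2 or 4, contralateral inhibitor replicate 2 or 3, MIA vehicle replicate 2, 3 or 4, or MIA inhibitor replicate 1. With the mean level of the co-varying set as a covariate, 67 transcripts were called for the interaction and 809 for both treatments, but this covariate largely repeats the contralateral vehicle group. With limma-trend on log2(TPM + 1) the counts were 7858 (1252 higher and 6606 lower) and 11127 (9660 higher and 1467 lower). With limma-voom on counts they were 8457 and 10256.

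Inhibitor was compared with vehicle within each kind of knee. In MIA knees edgeR's quasi-likelihood test called 0 transcripts (n = 4 against 4), with a smallest adjusted p of 0.0993 and 2335 transcripts at an unadjusted p under 0.05, where 1348 are expected by chance. The median absolute log2 change of the 7860 transcripts called in vehicle rats was 0.25 here. Other tools called 798 (DESeq2), 2061 (limma-voom) and 18 (limma-trend) transcripts. Without MIA vehicle replicate 1 the edgeR count was 180, and it was 1 without contralateral vehicle replicate 1 or 3 or MIA vehicle replicate 3. Without all 4 libraries that lie apart on the second component 369 were called, 141 higher and 228 lower with inhibitor.

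In contralateral knees, which received saline alone, 6440 transcripts were called between inhibitor and vehicle, 3269 higher and 3171 lower with inhibitor. The 125 co-varying transcripts had a median log2 change of -4.96 with a median SE of 2.00, and 26 of them were called, all lower. ENSRNOT00000059673.6 rose, since it had no count in contralateral vehicle knees, and ENSRNOT00000089142.2 and ENSRNOT00000117239.1 fell to no count with inhibitor (edgeR adjusted p = 4.48e-07, 0.00196 and 0.000673), while ENSRNOT00000011727.7 had no count in either group. With DESeq2 size factors in the edgeR fit the split was 2429 higher and 3777 lower, and with limma-trend on log2(TPM + 1) 9882 and 1854. The count was 4224 without contralateral vehicle replicate 2 and 3951 without replicate 4 of that group, and 3539 when the 8 libraries compared were fitted alone. It was 1420 with the mean level of the co-varying set as a covariate, which largely repeats the contralateral vehicle group. The near-even split of the main fit did not hold with the 8 libraries fitted alone or with the replicate block, where most calls were lower, as given under the processing alternatives.

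The transcripts that changed in this comparison overlapped those of the MIA comparison in vehicle rats. Of the 4289 and 3269 transcripts higher in the former comparison's MIA knees and the latter's inhibitor knees, 2150 were shared, and of the 3571 and 3171 lower ones 2580 were shared, where independent lists would share 520 and 420. Both comparisons use the 4 contralateral vehicle libraries, so part of this excess may come from them. The log2 changes had a correlation of 0.72 across transcripts and a covariance of 2.83, against 0.51 and 0.83 in simulated groups with no change, in which no transcript was called in both. With the 4 shared libraries split into pairs, so that each comparison used other libraries, the correlation was 0.40 to 0.45 over 6 fits and 1542 to 2592 transcripts were called in both in the same direction. The split removes only the variation of single libraries. A deviation common to all 4 contralateral vehicle libraries stays in both pairs, so the overlap cannot be told apart from it.

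Whether the inhibitor moved MIA knees back along the MIA change was examined by the correlation across transcripts of the MIA change in vehicle rats with the inhibitor's change in MIA knees. The correlation was -0.32 and the covariance -0.804. Simulated groups with no change gave a mean correlation of -0.49 (-0.52 to -0.47 over 10 simulations) and a covariance of -0.793, because the MIA vehicle libraries enter both changes with opposite sign. The covariance differed from the simulated one by -0.011, where the simulated groups were all drawn at a transcript's mean over the 16 libraries. With the 4 shared libraries split into pairs the correlation was between -0.24 and 0.01 over 6 fits and the mean covariance was -0.422, where separate libraries with no effect would give about 0. A deviation common to all 4 MIA vehicle libraries would stay in both pairs. The simulated and the split values thus differ in what they show, and whether the inhibitor moved MIA knees back stays undecided.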

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

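Of the tests in this part, those on abundant transcripts, on transcripts lost from 4 libraries, on numbered pairs and on the falls of over 4-fold were chosen only after the results were seen, and the 5% bound on the splits was set after the splits of the 4 comparisons of 4 against 4 libraries had been seen. The bounds behind the verdicts on the length trend and on the falls were adjusted after their values were seen. A comparison of estimated fragment lengths between MIA and contralateral knees of vehicle rats was looked at first as a sign of a batch (exact permutation p = 0.714, n = 4 against 4), and the test on lost transcripts took its place. Of 39 groups of 4 values tested for a library far from the others of its group, 10 held one, where chance gives about 1.95.

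Most of these values belong to 4 libraries, which form the first pattern. Their scores on the second principal component were -111 in contralateral vehicle replicate 1 (others 105 to 127.6), -116.1 in MIA vehicle replicate 1 (others 34.8 to 43.8), -192.7 in contralateral inhibitor replicate 4 (others 18.6 to 25.2) and -163.6 in MIA inhibitor replicate 4 (others 9.75 to 26.9). MIA vehicle replicate 1 had 27254 transcripts above 0 (others 29506 to 29851), the TMM factors of contralateral and MIA inhibitor replicate 4 were 0.914 (others 1.18 to 1.22) and 0.925 (others 1.21 to 1.23), and the 100 most abundant transcripts of MIA inhibitor replicate 4 held 33.8% of its counts (others 25.7% to 26.4%).

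A trend with transcript length does not account for the whole of this pattern: the median correlation of deviations between the 4 libraries was 0.39 before and 0.385 after each library's length trend was removed, with the 6 pairs between 0.24 and 0.51 afterwards, and the trend held 1.71% of their variance on average. The 4 libraries form 2 whole pairs of same-numbered knees, a share of 0.0154 of all 1820 sets of 4 libraries, but this was seen before the test was chosen, so the share does not decide whether same-numbered knees share what sets them apart. In vehicle rats the correlations of same-numbered knees do not settle whether the numbers pair them, and no label says that a number marks a rat. The source of this pattern stays open, technical or biological.

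ENSRNOT00000011727.7 was at 50.1 CPM in MIA vehicle replicate 2 (others 26.0 to 29.7) and at 74.8 CPM in MIA inhibitor replicate 3 (others 0.413 to 1.42).

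The MIA change differed between inhibitor and vehicle rats by the interaction test for 2668 transcripts, and this goes with the second pattern, that the 4 contralateral vehicle libraries lie apart from the other 12. Counts taken up by abundant transcripts cannot account for all rises: the largest share of the 100 most abundant transcripts, 53.1%, bounds such a rise at 2.13-fold, and 27.1% of the called rises of vehicle rats (1164 of 4289) lay beyond the bound by more than 2 SE. A further source of RNA, tracked by the co-varying set, stays open as a source of the falls: in the 12 libraries without the 4 above, the called falls outside the set followed the set's score within groups with a median correlation of 0.0637 (exact one-sided permutation p = 0.197), and those of over 4-fold with 0.228 (exact one-sided permutation p = 0.00926). The called rises outside the set followed it with 0.0983 (exact one-sided permutation p = 0.188), more than all called falls but less than those of over 4-fold. All tested transcripts outside the set gave 0.0277. Other animals or another genotype cannot be told apart from the group: 8 transcripts had no count in the 4 contralateral vehicle libraries and more than 1 CPM in the other 12, and 9 had the reverse. The 4 libraries of the first pattern had 9 and 1, so the 8 is not the highest of all sets of 4 libraries. The next set had 3 and 1. For the reverse, the 9 of the contralateral vehicle libraries was the highest, with at most 2 in any other set. A separate batch of these libraries is confounded with the group, and a true difference between the contralateral knees of vehicle rats and all other knees also stays open, untested.

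Other splits of the same libraries gave the following. In the MIA comparison of vehicle rats the real split alone called as many as 7860 (1 of 35 splits, highest other 3). The same holds for inhibitor against vehicle in contralateral knees, with 6440 (1 of 35, highest other 1526). Both counts rest on the same 4 contralateral vehicle libraries, so they are not separate results. The real splits stand out, but 1 of 35 is the smallest share possible and the bound was set after these splits were seen. The splits therefore do not exclude chance at a bound fixed beforehand. For the MIA comparison of inhibitor rats 14 of 35 splits called at least as many as the real 1 (highest other 3; highest 2 among the 8 splits that part all numbered pairs, in which knees are exchanged between groups within a number), so chance cannot be excluded. In MIA knees the real count of inhibitor against vehicle was 0, so all 35 of 35 splits call as many by construction and nothing is decided on chance. Of these splits 1 called 123, for a reason that was not tested, while the other 14 that also held both libraries of the first pattern on the same side called at most 2. For the interaction, 2 of 60 regroupings, the real one included, called at least the real 2668 (highest other 3474). For both treatments 1 of 60, the real one, called at least the real 5300 (highest other 4226). Regroupings that divided the contralateral vehicle libraries called at most 1 and 3 transcripts, so these shares rest on the same libraries as the splits above. They do not test either comparison apart from the 4 contralateral vehicle libraries, and chance is not excluded. Of the regroupings that kept these 4 together, 3 for the interaction called 3474, 1685 and 1515, so chance is not excluded there for the other 12 libraries, and 2 for both treatments called 4226 and 3171, too few to decide.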

How the results depend on the processing

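The alternatives without the 4 libraries that lie apart, with a term for them, without the most abundant transcripts and with the co-varying set as a covariate were chosen after the data were seen; covariates from muscle and fat marker lists, and all alternatives for gene lists, were not run because the transcripts have no gene names. Except where a count is printed here, each count was within 1.5 times its main value, and the cause of the differences was not tested. Of the 4 named transcripts, none changed direction, and ENSRNOT00000011727.7 alone missed the threshold, with the covariate (adjusted p = 0.0834, range over its alternatives 0.000214 to 0.0834), where its log2 change was 14.4 ± 4.16 (SE) against 12.9 ± 3.04 (SE). This transcript had no count in any contralateral library, so these estimates do not show whether its change became larger or smaller. It got no adjusted p from DESeq2, and the stricter filter removed it and both named falls. For MIA against contralateral knees in vehicle rats (main 7860) limma-voom called 12910, limma-trend on TPM 14001 and the covariate fit 2015. In inhibitor rats (main 1) DESeq2 called 328, limma-voom 358, limma-trend 19, the replicate block as a random effect 19, the term for the 4 libraries 2 and the fit without them 91, while no filter, the stricter filter, only the groups compared and the replicate block as a fixed effect each called 0. For inhibitor against vehicle in MIA knees (main 0) DESeq2 called 798, limma-voom 2061, limma-trend 18, the random block 4, only the groups compared 3 and the fit without the 4 libraries 369. In contralateral knees (main 6440) limma-voom called 11463, limma-trend 11736, only the groups compared 3539 (1080 higher, 2459 lower), the replicate block 1469 (222 higher, 1247 lower), the fit without the 4 libraries 10865 and the covariate fit 1420. For the interaction (main 2668) DESeq2 called 4933, limma-voom 8457 (3762 higher, 4695 lower), limma-trend 7858, the random block 4973, the fit without the 4 libraries 6880, the term for them 5196 (2561 higher, 2635 lower) and the covariate fit 67 (49 higher, 18 lower). For both treatments (main 5300) limma-voom called 10256, limma-trend 11127, the random block 7995, the fit without the 4 libraries 9061, the term for them 8142 and the covariate fit 809 (632 higher, 177 lower). Of the calls of the covariate fit in vehicle rats, 1884 were also called without it. The covariate's values did not overlap between the contralateral vehicle libraries and the others, so its lower counts do not separate the set from the group.

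Leaving out each library gave 5717 to 9535 calls for the MIA comparison in vehicle rats, 0 to 6 in inhibitor rats, 0 to 180 for inhibitor against vehicle in MIA knees, 3951 to 8959 in contralateral knees, 1451 to 5484 for the interaction and 3955 to 7423 for both treatments. The slope of the MIA changes over transcripts called in both treatments together was 0.24 to 0.36 (main 0.29, jackknife error 0.13), and the correlation of the MIA change with the inhibitor's change in MIA knees -0.49 to -0.23 (main -0.32, jackknife error 0.19). With DESeq2 size factors they were 0.29 and -0.32, and with the stricter filter 0.17 and -0.27.

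Vehicle rats' same-numbered knees had correlations of deviations of 0.24, 0.08, 0.10 and 0.02, and 2 of the 4 contralateral vehicle libraries correlated best with their own number. Pairing was thus neither shown nor excluded in this treatment. The replicate block gave 9158 calls in vehicle rats, 2957 for the interaction and 6325 for both treatments. Between inhibitor and vehicle knees, same-numbered libraries correlated at -0.25 to 0.26 in MIA knees and -0.16 to 0.11 in contralateral knees, with 1 of 4 best with its own number in each. The block left 0 calls in MIA knees. Only in inhibitor rats were the numbers taken to pair the knees.

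Few transcripts of low abundance were called: those below 1 CPM on average made up 4829 of those tested and 352 of the 7860 calls in vehicle rats. Transcripts whose counts were whole in every library were called in 36.0% of 3187 cases, against 28.2% of the others.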

Other observations

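The tests in this part were chosen after the results were seen. The MIA change of vehicle rats was looked for in the inhibitor rats, whose libraries it does not share. Of the 7860 transcripts called in vehicle rats, 69.4% had a difference of the same sign between MIA and contralateral inhibitor knees, with a median difference of 0.12 log2 CPM in the direction of the vehicle rats. For the 4289 that rose in vehicle rats the share was 71.9% with a median of 0.15, and for the 3571 that fell it was 66.4% with a median of 0.09. Over all 26956 tested transcripts the share was 59.7%.

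A hypothesis is that the direction of the MIA change may recur in inhibitor rats at a smaller size. Across the 7860 transcripts the correlation of edgeR's change in vehicle rats with the difference of mean log2 CPM in inhibitor rats was 0.413 (0.34 with edgeR's change in both), with an exact two-sided permutation p of 0.143 over the 35 splits of the 8 inhibitor libraries (n = 4 against 4), and the highest of the other splits gave 0.505 in absolute value. For the 4289 rises the correlation was 0.34 with an exact permutation p of 0.0571 (n = 4 against 4; highest other 0.36), and for the 3571 falls 0.15 with a p of 0.743 (n = 4 against 4; highest other 0.41). When knees are exchanged only within the sample numbers, which were taken to pair them in inhibitor rats, only 8 splits are left, too few for a p under 0.05. The real split had the highest correlation of the 8 for all 7860 (next 0.376) and for the rises (next 0.308), and for the falls 4 of the 8 were as large in absolute value (n = 4 pairs). None of these tests passed 0.05, so the hypothesis stays open with these libraries.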
